A study of Mus musculus with 2 samples.

How the data were processed

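DNase-seq measures how readily the nuclease DNase I cuts DNA in isolated nuclei, so that stretches of open chromatin, such as active promoters and enhancers, appear as peaks of cut sites. The assay was run on whole adrenal glands of female mice aged 36 days, from the F1 hybrid strain B6CASTF1/J, a cross of C57BL/6J with the wild-derived strain CAST/EiJ. The adrenal gland has a cortex, which makes steroid hormones, and a medulla, whose chromaffin cells make catecholamines. The labels give 1 group of 2 libraries, called biological replicates 1 and 2. They number the animals differently and give both the same donor record, so that the replicates were taken as separate animals of 1 stock. No second tissue, sex, age or treatment was analysed here. The comparisons were therefore between the replicates, and between sets of genes or sites within each library.

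For each library the files used here were a pair of peak lists, a table of false discovery rates along the genome and a list of footprints, which are short stretches protected from cutting inside open chromatin. Per the labels and the text deposited with each sample, all were on the mouse assembly mm10, and each was made from that library's own filtered alignments, with no pooling of replicates. The aligner, the peak caller, their versions and their thresholds are not given in the sources used here. The unit of the deposited peak heights is a signal, which the authors scaled in some way before deposit. Within each library 100% of the heights were whole multiples of 1 step, with a tolerance of 0.01 steps, and the step was 0.00934 in replicate 1 and 0.00883 in replicate 2. If a step stands for 1 tag in a signal scaled to 1000000 tags, which is an inference from the values alone, the libraries held about 107000000 and 113300000 tags. The number of reads itself was not analysed here, so that no counting interval can be given for a single height. The values of the deposited table of false discovery rates are p-value-like numbers (q-values), and only positions under 0.05 are listed. In the deposited footprint lists the p-value column held the constant 0.01, so that footprints could not be ranked.

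The 2 peak lists of a library were told apart by testing them against the table of false discovery rates. Every peak of the longer list touched a position under 0.05, and every peak of the shorter list touched one at or under 0.001. The longer list was used throughout because it had the equal or narrower median peak width, as the plan asked, and the shorter list was an alternative. Positions at or under a false discovery rate of 0.05 stood in for the broad regions named in the plan. The chromosome lengths of the reference used here (GRCm38.p6) were at least as long as the last peak on each chromosome. Genes and transcription start sites (TSS) came from the basic set of GENCODE release M21 for that assembly, with 21911 protein-coding genes.

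All computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Peaks of the replicates were called shared when they overlapped by at least 1 bp. The chance level came from 20 shifts of the peaks of replicate 2 along the same chromosomes. Heights were compared on the log2 scale between each peak of replicate 1 and its strongest overlapping partner in replicate 2, which can serve several peaks, with no pseudocount. Peaks were assigned by their centre to promoters (within 1 kb of any annotated TSS), then exons, introns and the space between genes, against the share of each class in the genome without gaps. The promoter height of a gene was the height of its strongest peak that reached within 1 kb of any of its TSS, or 0 with no peak. Its distal peaks were those inside its domain with their centre over 1 kb from any TSS. The domain is the gene body with flanks of up to 50 kb that stop at the next TSS of another protein-coding gene. A peak that reached into the promoter window with its centre outside it, such as that of Apoa2, counted in both measures.

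A total of 22 gene lists and 26 sequence consensuses were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The lists cover steroidogenesis, cholesterol synthesis and uptake, the zona glomerulosa, the X-zone, adrenal transcription factors, chromaffin cells of the medulla, capsule and stroma, Schwann and sustentacular cells, endothelium, macrophages, lymphocytes, erythroid cells, adipocytes, kidney, liver, skeletal muscle, central neurons, ovary, the circadian clock, immediate early genes, housekeeping genes and olfactory receptors. A list's median was placed among 10000 random lists of the same size, matched on promoter CpG content in 5 groups for promoter heights and on domain length in 10 groups for distal peaks. For the olfactory receptors 1000 random lists were drawn. Genes and peaks are not replicates, so that these percentiles describe the 2 libraries and no p-value was computed. Tested on simulated lists of 15 genes made from the promoter heights of 21911 genes in replicate 1, the procedure placed 1.50% of unchanged lists above percentile 97.5, 29.5% of lists with heights multiplied by 2 and 68.5% of those multiplied by 4.

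The rule for named genes took 15 genes of the adrenal cortex and medulla in every case. From each list it also took the 2 genes with the highest mean promoter height and the gene with the lowest. A few genes and 1 consensus are not reported here, though the genes count in the values of their lists. The rule also took the 5 genes with the most distal peaks, and the genes nearest to the 5 strongest distal peaks and to the 3 strongest peaks found in each replicate alone. For each named promoter, the share of its 32-mers that occur once in the reference was computed, since reads from near-identical copies of a sequence cannot be placed with certainty.

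Consensus matches were exact, on either strand. Footprints were widened by 5 bp on each side and compared with intervals of the same width moved by 50 bp within the same peak that touched no footprint. The ratio of the shares has an exact binomial (Clopper-Pearson) 95% interval, which covers counting error only. The central 150 bp of promoter and distal peaks was compared with up to 20 shuffled consensuses of the same base and CpG content. Values are given per replicate or as the mean ± SD over the 2 replicates, and an SD from 2 values is itself imprecise. Alternatives changed 1 choice at a time, and the closing section gives their effect.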

Results

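Chromatin accessibility was measured by DNase-seq in whole adrenal glands of female B6CASTF1/J mice aged 36 days, in 2 libraries that form 1 group as biological replicates 1 and 2. Replicate 1 had 157595 peaks of a median width of 180 bp that covered 1.08% of the genome, and replicate 2 had 166206 peaks of 171 bp that covered 1.09%. The step between the deposited peak heights would put the libraries at about 107000000 and 113300000 tags, an inference from the values alone. Height is the authors' signal for a peak, in the same unit throughout. Positions are on mm10 and, unless stated, are those of replicate 1. Errors are SDs over the 2 replicates, and for heights they include the general shift between the libraries given below. With 2 replicates and no second condition no p-value was computed, and gene lists were placed among random lists of equal size within each library.

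Most genes of steroid hormone synthesis had open promoters in both glands. Of the 14 genes of the steroidogenesis list, 13 had a promoter peak in replicate 1 and 12 in replicate 2, shares at percentiles 99.98 and 99.4 of random lists. The median promoter height of the list was 6.46 in replicate 1 and 10.6 in replicate 2, where random lists of the same promoter CpG content had medians of 1.94 and 2.86. These values lay at percentiles 97.9 and 98.8 of the random lists. Nr5a1, which encodes the transcription factor SF-1 that governs the steroidogenic program, had a promoter height of 9.14 ± 3.57 (mean ± SD, n = 2) at 2:38714441–38714620. Star, whose product carries cholesterol into mitochondria, reached 7.69 ± 1.96 at 8:25808441–25808580. Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, reached 7.81 ± 2.35 at 9:58014881–58015100. The tallest promoters of the list belonged to Por, at 24.7 ± 5.72, and Fdxr, at 19.7 ± 4.73, which pass electrons to cytochrome P450 enzymes. The promoter of Cyp21a1, the 21-hydroxylase, reached 4.33 ± 1.02, and that of Cyp11b1, the 11β-hydroxylase of corticosterone synthesis, 2.65 ± 0.0473. Hsd3b1, a 3β-hydroxysteroid dehydrogenase, had no promoter peak in either library. Mc2r, the receptor for the pituitary hormone ACTH, had a peak of 0.757 in replicate 1 and none in replicate 2. In both libraries Hsd3b1, Mc2r, Cyp11b1 and Nr0b1 (0.981 and 1.17) lay below the median promoter height over all protein-coding genes (2.96 and 4.45). Star, Cyp11a1 and Cyp21a1 lay above that median but below the median of the list in both libraries. Against random lists not matched on CpG content the mean percentile of the list was 88.6, inside the central 95% of the random lists. The 32-mers around the TSS that occur once in the genome were 66.3% for Cyp21a1 and 77.3% for Cyp11b1, and reads from near-identical copies cannot be placed with certainty there.

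Cholesterol genes stood out further. All 14 genes of cholesterol synthesis and uptake had a promoter peak in both replicates. This share lay at percentiles 68.7 and 65.3, since random lists of the same CpG content also had a median share of 100%. The median heights of the list were 15.5 and 22.8, at percentile 99.98 in each. Srebf2, the regulator of sterol synthesis genes, had a promoter height of 22.7 ± 5.81, and Cyp51, a lanosterol demethylase and the lowest of the list, 9.76 ± 3.75. The tallest, 28.5 ± 7.87 at Dhcr7, lay nearer to the TSS of the neighbouring gene Nadsyn1. All 11 adrenal transcription factor genes also had a promoter peak in both libraries, a share at percentiles 66.4 and 63.5. Their medians of 6.62 and 10.9 lay at percentiles 25.9 and 36.1. Among them Nr4a1, a nuclear receptor induced by trophic hormones, was the tallest at 20.1 ± 6.46, followed by the transcriptional co-regulator Cited2 at 16.1 ± 3.99, and Tcf21, a gene of the capsule and stroma, was the lowest at 0.469 ± 0.0510.

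Most markers of the zona glomerulosa and the X-zone had an open promoter. Of the 12 genes of the zona glomerulosa, the outer zone that makes aldosterone, 10 and 11 had a promoter peak, shares at percentiles 77.2 and 96.4, and the medians of 2.70 and 4.16 lay at 13.6 and 14.2. Kcnk3, a potassium channel of that zone, reached 8.13 ± 0.815, and the signalling gene Wnt4 7.82 ± 2.78. Cyp11b2, the aldosterone synthase, had no promoter peak in either library, and 75.5% of its promoter 32-mers occur once. All 4 genes of the X-zone, an inner cortical zone of young female mice, had a promoter peak, a share at percentiles 99.8 and 99.8, with medians of 2.45 and 3.16 at 92.9 and 91.1. Akr1c18, a progesterone-converting enzyme used as the X-zone marker, reached 1.93 ± 0.468 at 13:4150621–4150800. Thrb, a thyroid hormone receptor, reached 11 ± 2.44, the cytochrome P450 gene Cyp2f2 3.68 ± 0.545, and the lipid kinase gene Pik3c2g 0.771 ± 0.179. Cyp17a1, the 17α-hydroxylase that the adult mouse adrenal uses little and the gonads use, had a promoter peak of 2.10 ± 0.429. Without matching on CpG content the mean percentile was 45.7 for the zona glomerulosa list, 36.4 for the X-zone list and 85.7 for the adrenal transcription factors, against 13.9, 92.0 and 31.0 with it, all inside the central 95%.

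Promoter peaks of the medulla genes were frequent but low for the CpG content. Of the 22 chromaffin genes 19 and 20 had a promoter peak, shares at percentiles 76.8 and 89.6, but their median heights were 1.16 and 1.62 against 4.53 and 6.86 in random lists, at percentiles 0.62 and 0.41. Th, the rate-limiting enzyme of catecholamine synthesis, had a promoter height of 0.863 ± 0.177, and Dbh, which makes noradrenaline, 1.07 ± 0.0981. Pnmt, which makes adrenaline, had a peak of 0.662 in replicate 2 and none in replicate 1, and the decarboxylase gene Ddc had none in either. Chga, a chromogranin of secretory granules, differed between the replicates with 2.17 and 6.40, and Chgb, another granule protein, reached 13.7 ± 4.68. The tallest promoter of the list, 21.6 ± 5.43 at Slc18a1, lay 551 bp from the TSS of this vesicular monoamine transporter and 25 bp from that of Atp6v1b2. Without matching on CpG content the mean percentile of the list was 16.9, inside the central 95%.

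**Figure D1:**
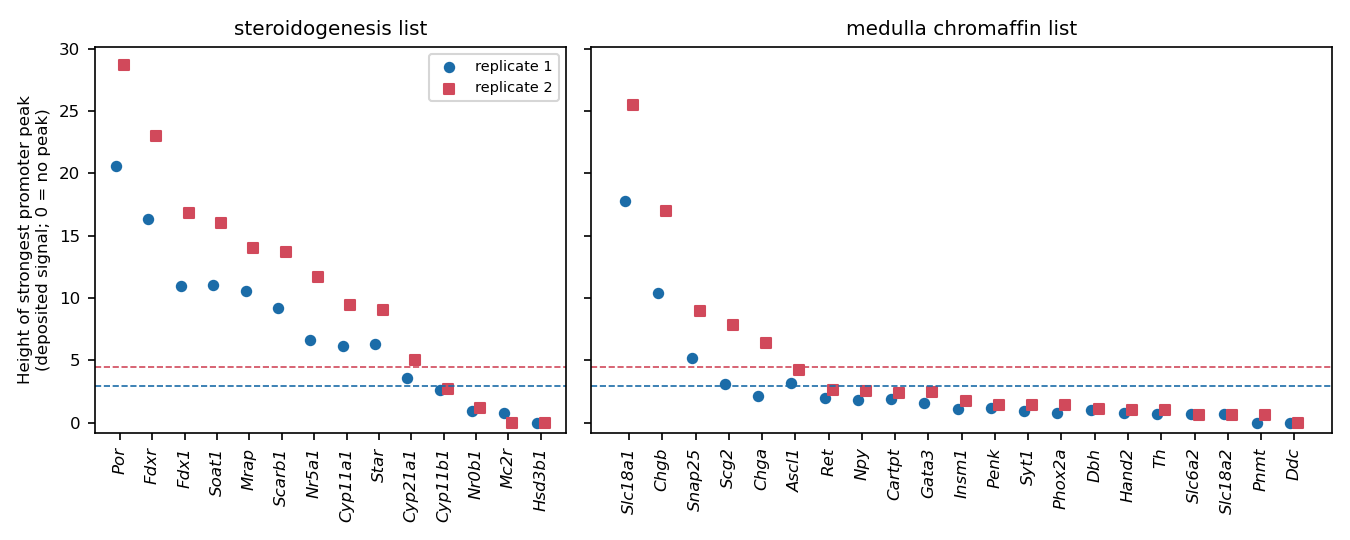
Height of the strongest promoter peak of 14 genes of the steroidogenesis list and 21 of the medulla list in both replicates (vertical axis, deposited signal, 0 where there was no peak), with dashed lines at the median over 21911 protein-coding genes (2.96 in replicate 1 and 4.45 in replicate 2). Star, Cyp11a1 and Nr5a1 lie above both lines, while Th, Dbh and Pnmt lie below them.

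Genes of the circadian clock and of the immediate response to stimuli had tall promoters. All 13 circadian clock genes had a promoter peak in both libraries, a share at percentiles 84.2 and 82.65. Their medians of 15.4 and 23.6 lay at percentiles 99.87 and 99.97. Nr1d1, a repressor within the clock, reached 29.3 ± 8.78, the clock output factor Tef 25.5 ± 8.02, and Clock, the lowest, 11.4 ± 4.41. All 8 immediate early genes had a peak, a share at percentiles 58.4 and 56.0, with medians of 14.6 and 21.6 at percentiles 98.3 and 98.4. Atf3, a stress-induced factor, reached 31.5 ± 9.53 and Egr1, a growth-factor response gene, 22.8 ± 6.80, while Fos was the lowest at 6.41 ± 1.48. With a window of 500 bp the mean percentile of the immediate early list was 96.8, just inside the central 95%. All 14 housekeeping genes had a peak, a share at percentiles 71.7 and 67.7, with medians of 11.7 and 16.8 at percentiles 95.8 and 93.3. The mean percentile of the housekeeping list was 99.7 without matching on CpG content, above the central 95%. Among them the ribosomal protein gene Rplp0 reached 25.8 ± 6.32, the actin gene Actb 23.2 ± 4.75 and the X-linked glycolytic gene Pgk1 7.68 ± 2.87.

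The marker lists of supporting and blood-borne cells had lower median promoter heights than the steroidogenesis list. Of the 10 genes of capsule and stroma 7 and 8 had a peak, shares at percentiles 90.2 and 98.1, and the medians of 0.972 and 1.5 lay at 62.9 and 67.2. The mesenchymal receptor gene Pdgfra reached 7.33 ± 2.59, the Hedgehog receptor gene Ptch1 6.47 ± 1.75, and Col3a1, a collagen, had none. Of the 13 endothelial genes 12 and 13 had a peak, shares at percentiles 97.1 and 99.6, with medians of 1.82 and 2.27 at 34.8 and 28.8. The VEGF receptor genes Flt1 and Kdr reached 5.51 ± 1.58 and 3.36 ± 0.519, and the adhesion gene Pecam1 had a peak of 0.830 in replicate 2 and none in replicate 1. Of the 14 macrophage genes 4 had a peak in replicate 1 and 9 in replicate 2, shares at percentiles 38.5 and 99.4, and their medians of 0 and 0.494 lay at 44.4 and 96.9. The lysosomal gene Cd68 reached 2.00 ± 0.491 and Cd74, the invariant chain, 1.17 ± 0.492, whereas Csf1r, the receptor for a macrophage growth factor, had none. Of the 10 lymphocyte genes 1 and 2 had a peak, shares at percentiles 3.2 and 11.03, and the medians of 0 lay at 35.0 and 32.7. Zap70, a T-cell kinase, had 0.382 ± 0.0154, and Lck, another, had 0.891 in replicate 2 alone. Of the 8 erythroid genes 2 had a peak in each library, shares at percentiles 45.6 and 42.5, and the medians of 0 lay at 43.6 and 42.7. Epor, the erythropoietin receptor gene, reached 2.05 ± 0.964, while Alas2 of haem synthesis had none. Of the 7 Schwann and sustentacular genes 2 and 4 had a peak, shares at percentiles 2.2 and 50.4, and the medians of 0 and 0.530 lay at 16.5 and 39.8. The growth factor receptor gene Erbb3 reached 2.54 ± 1.14, and Cdh19 had none. Without matching on CpG content the mean percentiles of the medians were all inside the central 95%. They were 20.6 for capsule and stroma, 33.3 for endothelium, 4.86 for macrophages, 2.94 for lymphocytes, 3.06 for erythroid cells and 11.6 for Schwann cells. A median of 0, as of lymphocyte and erythroid genes, is the lowest possible, and random lists reached it too. Such a list could not fall below the central 95%.

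Most markers of kidney, liver and the nose had no promoter peak, whereas most of those of ovary and fat had one. Of the 9 central neuron genes 5 had a peak in each library, shares at percentiles 1.35 and 0.855, with medians of 0.505 and 0.671 at 0.69 and 0.53. The glutamate transporter genes Slc17a6 and Slc17a7 had 5.02 ± 2.22 and 1.52 ± 0.639, and Neurod6 had none. Without matching on CpG content the mean percentile of this list was 15.4. Kidney genes had a peak in 3 and 5 of 13 cases, shares at percentiles 0.125 and 5.55, and medians of 0 at 16.1 and 13.7, with 0.978 ± 0.365 at the water channel gene Aqp2, 0.542 ± 0.119 at the endocytic receptor gene Lrp2 and none at Cubn. Liver genes had a peak in 3 and 2 of 13 cases, shares at percentiles 6.19 and 0.83, and medians of 0 at 38.8 and 37.1. The apolipoprotein gene Apoa2 had 4.22 ± 0.908, the plasma protein gene Ahsg none, and the peak of 15.6 ± 1.30 at Foxa3 lay nearer to the TSS of Sympk. Muscle genes had a peak in 5 and 6 of 11 cases, shares at percentiles 23.1 and 42.8, and medians of 0 and 0.574 at 16.9 and 45.2, with 5.28 ± 2.91 at the creatine kinase gene Ckm, 1.06 ± 0.00233 at the titin gene Ttn and none at Acta1. Ovary genes had a peak in 6 of 8 cases in each library, shares at percentiles 85.3 and 82.9, and medians of 0.850 and 1.09 at 57.2 and 55.5, with 4.76 ± 2.55 at the hormone gene Amh and none at its receptor gene Amhr2. Adipocyte genes had a peak in 9 of 10 cases in each library, shares at percentiles 99.2 and 99.0, and medians of 1.68 and 1.63 at 51.1 and 36.7, with 16.5 ± 5.92 at the lipase gene Lipe, 16.4 ± 4.25 at the transcription factor gene Cebpa and none at Adipoq. With random lists not matched on CpG content the mean percentiles of the medians were 3.89 for kidney, 3.89 for liver, 8.45 for muscle, 18.1 for ovary and 26.6 for adipocytes. Of 1134 olfactory receptor genes, which are used in the nose, 51 and 57 had a promoter peak, below all 1000 random lists. Olfr12 was the tallest of them at 9.63 ± 3.0, followed by Olfr1418 at 3.31 ± 0.00774, and Olfr1 had none.

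**Figure D2:**
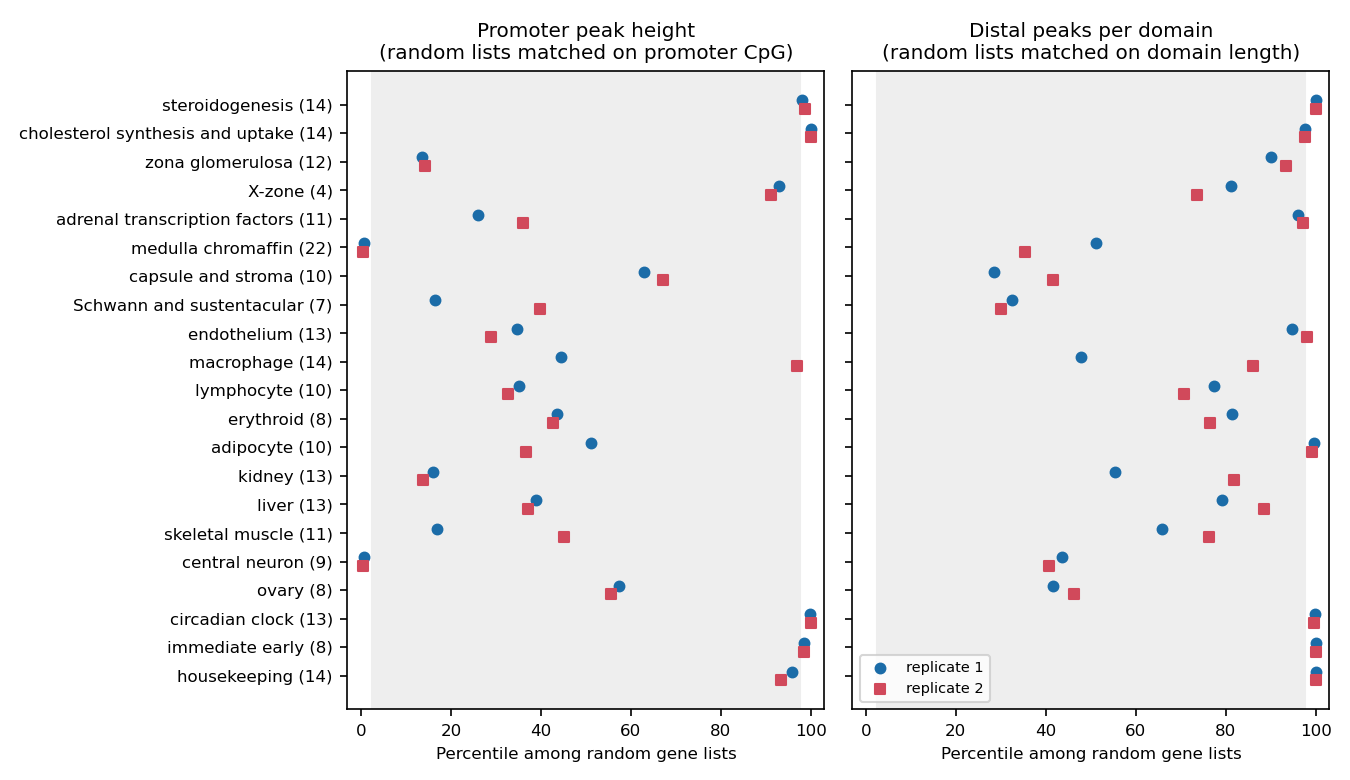
Percentile of each gene list (number of genes in brackets) among random lists of the same size, for the median promoter height (left) and the median number of distal peaks per gene domain (right), in both replicates, with the central 95% of the random lists shaded. The steroidogenesis list lies above the shaded range in both panels, while the medulla list lies at percentiles 0.62 and 0.41 on the left and 51.1 and 35.3 on the right.

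Distal open sites were dense around steroidogenic genes. Genes of the steroidogenesis list had a median of 13.5 distal peaks per domain in replicate 1 and 17 in replicate 2, where random lists matched on domain length had 5, and no random list reached as many (percentile 100 in both). The domain of Cyp11a1 held 20 and 27 distal peaks, the tallest in its own intron at 9:58009041–58009280 with heights of 7.95 and 10.2. The domain of Nr5a1 held 20 and 23, the tallest between genes at 2:38658581–38658740, 53.6 kb from the TSS, with heights of 5.95 and 8.31. The domain of Star held 16 and 23. Its tallest, 8:25806181–25806580 with 6.25 and 12.2, lay 2.09 kb from the TSS used here and over the annotated start of the gene at 25806555. Cyp21a1 had 19 and 25 distal peaks and Cyp11b1 had 14 and 13. Hsd3b1 and Mc2r, without tall promoter peaks, had 13 and 16 and 10 and 10, and near Mc2r a peak at 18:68474721–68474920 reached 3.49 and 3.09.

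**Figure D3:**
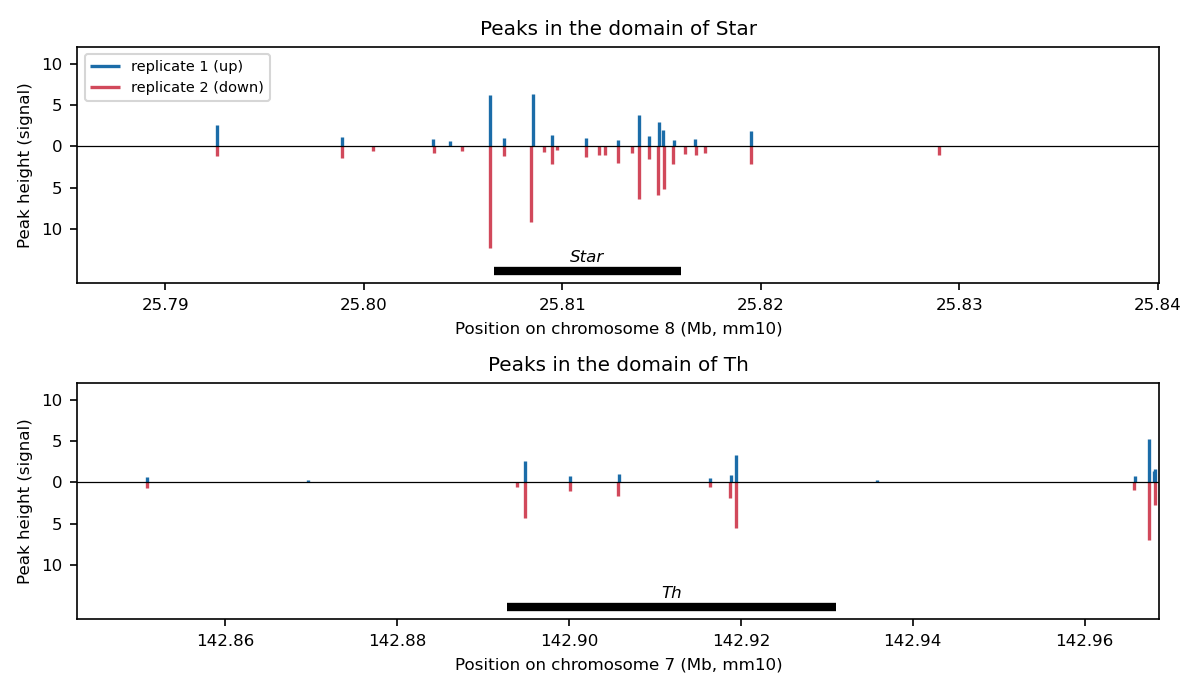
Height (deposited signal, vertical axis) and position (horizontal axis, Mb on mm10) of the peaks in the domains of Star and Th, replicate 1 drawn upwards and replicate 2 downwards, with a black bar for the gene. The domain of Star holds 17 and 26 peaks in all and that of Th 13 and 11.

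Other lists also had many distal peaks for the length of their domains. Immediate early genes had medians of 12.5 and 14 at percentile 100, with a peak of 13.9 and 20.8 at 12:85486021–85486240, 12.2 kb from Fos. Circadian genes had a median of 10 in both libraries at percentiles 99.9 and 99.7, and the domain of Nr1d1 held 23 and 37, among them an intronic peak of 29.1 and 40.8 at 11:98773781–98774120. Housekeeping genes had 8 and 9 at percentiles 99.9 and 99.97, adipocyte genes 9.5 in both at 99.5 and 99.0, and cholesterol genes 8.5 and 9 at 97.6 and 97.6. The medians of zona glomerulosa genes (11 and 12), adrenal transcription factor genes (11 and 12) and endothelial genes (11 and 13) lay at percentiles 89.9 and 93.3, 95.9 and 97.1, and 94.6 and 98.0. Kcnk3 alone had 49 and 78. X-zone genes had medians of 14.5 and 13.5 at percentiles 81.1 and 73.5, with 7 and 5 at Akr1c18 and 37 and 31 at Thrb. Medulla genes were not set apart, with medians of 6 and 5.5 at percentiles 51.1 and 35.3. The domains of Th (10 and 9), Dbh (13 and 14) and Chga (8 and 14) held fewer than that of Ddc, with 20 in both and an intronic peak of 6.78 and 9.04 at 11:11844461–11844720. The lists of capsule and stroma (28.4 and 41.7), Schwann cells (32.5 and 29.9), macrophages (47.8 and 85.9), lymphocytes (77.3 and 70.6), erythroid cells (81.3 and 76.4), kidney (55.3 and 81.9), liver (79.2 and 88.5), muscle (65.7 and 76.3), central neurons (43.5 and 40.6) and ovary (41.5 and 46.2) lay at percentiles inside the central 95%. Olfactory receptor genes had a median of 0 distal peaks in both libraries. With flanks of 10 kb the mean percentile was 35.5 for cholesterol genes and 92.7 for housekeeping genes, and without matching on length 96.9 and 96.1, with 96.6 for adipocyte genes. The cholesterol list was inside the central 95% with flanks of 200 kb (96.0) and among peaks above the median height (94.3) as well. The zona glomerulosa list rested on the choices made, with a mean percentile of 91.6, but of 99.1 with flanks of 10 kb, 98.7 with 200 kb, 99.6 without matching and 97.9 above the median height. The same alternatives gave the endothelial list 98.7, 98.3, 99.7 and 99.95, against 96.3, and the adrenal transcription factor list, at 96.5, lay at 98.1 with flanks of 10 kb and 99.2 without matching.

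The largest numbers of distal peaks lay in very long domains. There were 565 and 644 in that of Gm20388 (4482 kb) and 263 and 274 in that of the growth factor receptor gene Fgfr2 (3011 kb). Gm37240 had 118 and 113, the transcription factor gene Zfhx3 89 and 111 and the chromatin gene Gse1 86 and 106. A gene body is not cut at other genes inside it, so that such a domain can hold sites of those genes. Gse1 lies within Gm20388, and its sites count for both. The 5 tallest distal peaks were X:169997941–169998220 and X:169998261–169998420 in an intron of Mid1, nearest to Gm21887, 6:49236441–49236620 between genes near Igf2bp3, 9:123461921–123462100 in an exon of Lars2 near Limd1, and 13:112578161–112578320 in an intron of Il31ra. Their heights in replicate 1 were 42.0, 35.5, 41.4, 42.3 and 38.0, and those of their partners in replicate 2 were 76.3 for both sites on the X chromosome, which share 1 peak there, and 55.2, 51.4 and 41.8. Of the 32-mers in these 5 peaks 12.8% occur once in the genome, against 97.8% in the next 200.

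Across the genome, promoters held 22% ± 0.12 of the peaks (mean ± SD, n = 2) and 4.37% of the sequence, an excess of 5.03 times (5.01 and 5.05 in the replicates). The excess was 7.07 times with a window of 500 bp, 2.97 times with 2.5 kb, 6.29 times in the shorter lists and 7.11 times among peaks above the median height. Exons held 4.92% ± 0.34 of the peaks against 2.91% of the sequence, introns 41.4% ± 0.11 against 40.3% and the space between genes 31.7% ± 0.36 against 52.5%. Promoter peaks were the tallest, with median heights of 1.78 and 2.31 against 0.738 and 0.777 between genes. Of 21911 protein-coding genes, 68.6% and 69.6% had a promoter peak.

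The SF-1 consensus TCAAGGTCA was more frequent in footprints than beside them and was enriched at distal sites. A match to a consensus does not tell which factor was bound, and binding itself was not measured. Footprints numbered 297594 in replicate 1 and 298189 in replicate 2, with a median width of 10 bp, and 88.8% and 86.8% lay inside peaks. The SF-1 consensus was in 668 of 178295 footprints of replicate 1 and in 99 of the intervals moved aside, a ratio of 6.75 (95% interval 5.46 to 8.42), and in replicate 2 the ratio was 5.31 (4.31 to 6.60). In distal peaks it occurred 10.8 and 10.03 times as often as its shuffled versions, in 1.52% and 1.36% of the peaks, and in promoter peaks 5.37 and 4.93 times as often, in 0.443% and 0.403%. Against windows 1 kb away the mean ratio was 3.44 in distal peaks and 1.01 in promoter peaks, where the consensus was therefore no more frequent than beside the peaks. Without widening of the footprints the mean footprint ratio was 12.4, and against shuffled versions 42.1, compared with 6.03.

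Consensuses of other factors differed in where they were enriched. The AP-1 consensus, bound by Fos and Jun proteins, was in 16.1% and 13.7% of distal peaks, 5.05 and 4.42 times as often as its shuffled versions, and its footprint ratios were 4.21 and 3.31. CTCF, the insulator protein, had a footprint ratio of 94.9 ± 11.5 and was in 4.30% and 4.04% of distal peaks against 1.32% and 1.28% of promoter peaks. At promoters the SP/KLF consensus was in 9.79% and 9.69% of peaks and that of NFY in 10.8% and 10.2%, and the consensuses of ETS (14.1 and 13.6 times), NRF1 (19.5 and 17.8 times) and YY1 (37.7 and 41.3 times) were enriched over their shuffled versions. Against windows 1 kb away the mean ratios at promoters were 10.4 for ETS, 14.01 for NRF1 and 7.77 for YY1, so that the order of these consensuses depended on the control. CREB, the factor activated by cyclic AMP, had footprint ratios of 21.9 and 20.8 and was in 1.53% and 1.5% of promoter peaks against 0.378% and 0.402% of distal peaks. The NR4A consensus, whose factors share part of the SF-1 site, was enriched in distal peaks 3.79 and 3.16 times and in footprints 2.27 and 1.83 times. The GATA consensus was rarer in footprints than beside them (0.526 and 0.453) and was 1.24 and 1.28 times as frequent as its shuffled versions in distal peaks. Against windows 1 kb away the mean ratio in distal peaks was 5.56 for AP-1, 2.54 for NR4A and 1.06 for GATA. HNF4, a factor of liver and kidney, had footprint ratios of 1.00 and 0.778. Against shuffled versions the mean footprint ratio was 1.06 for GATA and 2.11 for HNF4, and for HNF4 it was 1.21 with controls moved by 100 bp, so that their direction depended on the control. Only 59.9% and 54.8% of footprints had a free interval to serve as control, and ratios that rest on 1 or 2 controls, such as those of NRF1 and NFI, are imprecise.

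**Figure D4:**
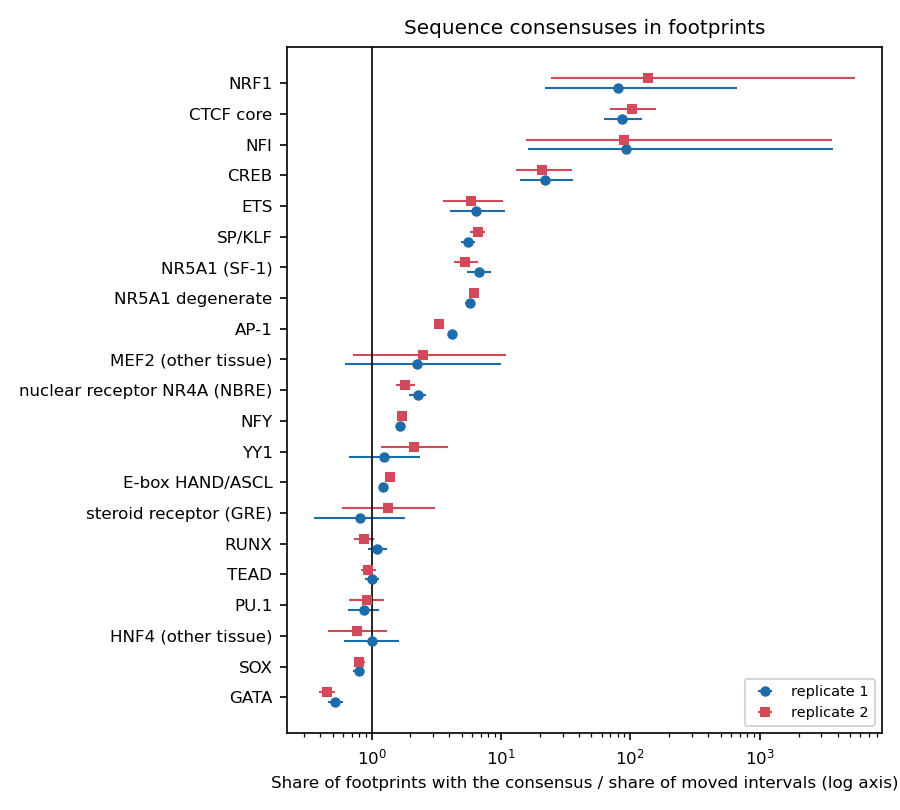
Share of footprints with a consensus, for 21 consensuses, over the share of same-width intervals moved by 50 bp (horizontal log axis), per replicate, with exact binomial 95% intervals that cover counting error only and a line at 1. CTCF, NRF1, NFI and CREB lie far to the right, the SF-1 site near 6, and GATA and SOX left of the line.

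The replicates shared most of their open sites. Of the peaks of replicate 1, 80.2% overlapped a peak of replicate 2, and 76.2% the other way, against 2.28% and 2.16% by chance. The Pearson correlation of log2 heights over 126336 overlapping pairs was 0.949 and the Spearman correlation 0.926, both across peaks, which are not independent replicates. Heights were higher in replicate 2 by a median of 0.38 on the log2 scale, by 0.55 at promoters and 0.27 between genes, so that heights of single genes were mostly higher in replicate 2 as well. Promoter heights of genes had a Spearman correlation of 0.989 across genes. Footprints were shared less, with 47.1% and 43.4% covered over at least 50% of their length by a footprint of the other replicate. After a move of the footprints of replicate 2 by 50 bp the shares were 11.5% and 16.1%. Only moved footprints still inside a peak were kept, so that fewer could cover those of replicate 1, which lowers the 11.5%. Positions under a false discovery rate of 0.05 spanned 46.4 Mb and 48.9 Mb, of which 38.5 Mb were shared, and under 0.001 they spanned 29.5 Mb and 31.6 Mb.

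No strong site was open in 1 animal alone. None of the 15782 peaks in the strongest 10% of replicate 1, and none of the 16638 in that of replicate 2, lacked both a peak and a position under 0.05 in the other replicate. Without a peak alone there were 23 and 62, and among the strongest 25% there were 18 and 20 peaks alone by both criteria. The tallest peaks of replicate 1 alone were 9:106716341–106716520 in an intron of Rad54l2 near Tex264, with 2.66, 19:5843001–5843180 in an exon of the noncoding gene Neat1 near Frmd8, with 2.56, and 7:68065121–68065320 in an intron of Igf1r, with 2.49. Those of replicate 2 alone were 11:96262581–96262760 in an exon of Gm53, nearest to the TSS of the body axis gene Hoxb9, with 4.49, 19:5823321–5823540, also nearest to Frmd8, with 3.24, and 11:96276001–96276220 in an exon of Hoxb9, with 3.11.

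The Y chromosome was nearly without peaks in these glands of female label. It held 29 and 24 peaks, or 0.329 and 0.272 per Mb against 64.1 and 67.5 on the autosomes, and its tallest, Y:90744601–90744820 with 10.8 and 11.1, had 8.47% of 32-mers that occur once. Of the Y peaks mostly made of such unique 32-mers there were 5 and 3, with heights of at most 0.850 and 0.980. In replicate 2 a peak of 0.0706 was listed in Zfy1, a Y-linked zinc finger gene, but 0% of its 32-mers occur once, so that its reads cannot be placed there with certainty. The X chromosome held 24.6 and 26.9 peaks per Mb, which alone does not tell the sex.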

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

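All alternatives in this part were planned before the data were examined, and the cause of the shifts was not tested. With 2 replicates, a value counts as shifted when it moved by more than 1 SD, itself an imprecise measure. For most values this is the SD between the replicates. For overlaps it is that between the 2 directions of comparison, and for the height correlation that over the chromosomes without Y. Numbers of distal peaks and of peaks in 1 replicate alone count as shifted when they changed by more than 1.5 times. Between the replicates, the mean share of overlapping peaks was 78.2%, and it was 70.8% with overlap of at least 50% of both lengths, 87.0% among peaks above each list's median height and 82.6% in the shorter lists. The correlation of heights was 0.916 over 1 kb from any TSS, against 0.949. Footprint sharing was 53.4% with 1 bp and 3.23% for identical intervals, against 45.3%. Positions spanned a mean of 47.6 Mb (46.4 to 48.9 without either replicate), 38.3 Mb at 0.01 and 30.6 Mb at 0.001. Peaks in 1 replicate alone numbered 0 in the strongest 10% and 5%, 38 in the strongest 25%, and 85 when a missing peak sufficed. The promoter share was 22% (21.9 to 22.1 without either replicate), 16.1% within 500 bp, 30.1% within 2.5 kb, 31.1% among peaks above the median height and 27.5% in the shorter lists, in each case above the share of the sequence. The ratio of Y to autosomal peak density was 0.00458 (0.00403 to 0.00513), 0.0017 above the median height and 0.00225 in the shorter lists.

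The placement of gene lists depended on the matching and, for distal peaks, also on the flank and on peak height. Without matching on CpG content the promoter percentile was 88.6 for steroidogenesis genes and 16.9 for medulla genes, both inside the central 95%, while the other alternatives gave 97.9 to 98.8 and 0.41 to 0.635. The distal percentile of steroidogenesis genes was 99.995 without matching on length and 100 otherwise. That of medulla genes was 43.2 (35.3 to 51.1 without either replicate), 81.1 with flanks of 10 kb, 70.3 with 200 kb, 77.9 without matching and 61.9 above the median height, always inside the central 95%. Of 21 lists, 17 stayed on the same side of the central 95% for promoters without matching, 20 with a window of 500 bp and 21 in the other alternatives. A list with a median promoter height of 0 could not fall below the central 95% there. For distal peaks 15 did so without matching, 16 with flanks of 10 kb, 18 with 200 kb, 18 above the median height, 20 without replicate 1 and 21 without replicate 2.

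The SF-1 ratio in footprints was 6.03 (5.31 to 6.75 without either replicate), 12.4 without widening, 4.29 with 10 bp and 42.1 against shuffled versions. In distal peaks it was 10.4 (10.03 to 10.8), 15.1 in the central 75 bp and 3.44 against windows 1 kb away. In promoter peaks it was 5.15 (4.93 to 5.37), 7.29 in the central 75 bp, 4.76 over whole peaks and 1.01 against those windows. Footprint ratios of GATA, SOX, RUNX, PU.1, TEAD, HNF4 and the steroid receptor crossed 1 under at least 1 alternative. C/EBP, REST, RFX and HNF1 had no match among the controls of at least 1 replicate, so that no mean ratio was formed. The planned comparison of stronger footprints was not run because their deposited p-value column is constant.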

Other observations

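The tests of GC content and of more chromaffin cells were chosen after the results were seen, as were the densest domains and the Hox clusters described first. Among domains of at least 50 kb, the densest in distal peaks were those of Slc35f6 and its neighbour Kcnk3, a potassium channel gene of the zona glomerulosa list, with 63.2 and 62.2 distal peaks per 100 kb as the mean of both replicates. These 2 domains overlap, so that they share sites. Other dense domains were those of Nr1d1 of the circadian clock with 55.9, Frmd8 with 47.4 and Tex44 with 39.6. Hoxb9 had 38.0 as a mean of 18.2 and 57.9, the cytokine receptor gene Tnfrsf1a had 38.0, and Star had 35.8. The Hox genes, which mark position along the body axis, held peaks in all 4 clusters, with 65 and 98 in Hoxb, 21 and 32 in Hoxc, 38 and 36 in Hoxa and 29 and 28 in Hoxd.

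At the level named in advance, the share of distal peaks with an SF-1 site was not set apart around steroidogenic genes. The hypothesis that it is higher there was therefore not borne out, but was not excluded either. The degenerate SF-1 consensus was in 7.97% and 7.91% of all distal peaks, and in 11.7% and 8.14% of those in the domains of steroidogenesis genes. These shares lay at a mean percentile of 69.5 among random lists (87.1 and 51.8), and those of medulla genes at 40.4 (56.1 and 24.6), all below the level named in advance. In number, 25 and 21 distal peaks with the consensus lay in the domains of 14 steroidogenesis genes, which held many distal peaks of any kind, so that the test speaks to the share and not to the number of sites per domain. With so few sites a modest excess in the share cannot be told from none. Distal peaks with the consensus had median heights of 0.860 and 0.918, and those without it 0.794 and 0.847.

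For the 5 distal peaks of replicate 1 with the greatest mean height, 2 of which share a partner in replicate 2, sequence present in several copies may account for the height. Of their 32-mers 12.8% occur once in the genome, while in the next 200 distal peaks 97.8% do. The design gives no second group, so that no biological explanation was tested, and open chromatin at 1 or more of the copies stays open.

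Peaks around medulla genes were slightly higher in replicate 2 than others of their class and height, with a median log2 difference of 0.11 at percentile 98.9. The GC content of the peaks may account for it, since with GC matched the median was 0.01 and the percentile 48.1. Before GC matching the medulla and X-zone lists did not stand alone. The zona glomerulosa list lay high, at percentile 97.51, and the erythroid list low, at 1.725. With GC matched these lists lay at 92.22 and 15.185. Across all peak pairs the log2 ratio between the replicates went with GC content (Spearman correlation 0.442), from a median of -0.11 in the lowest 10% by GC to 0.60 in the highest. More chromaffin cells in replicate 2 cannot be told apart from none, because random lists spread from -0.07 to 0.09 and a small excess would lie within that.

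Peaks around the 4 X-zone genes were lower in replicate 2 for their class and height, with a median log2 difference of -0.30 at percentile 0.05. With GC matched it was -0.21 at percentile 0.14, which argues against GC content as the whole reason. However, about 1 of 21 lists is expected outside the central 95% by chance. The X-zone list, the only one there with GC matched, was singled out after all were seen. Leaving out any of the 4 genes kept the percentile at 1.3 or lower. The list value is a median over genes, which 1 gene alone could hardly carry, so that this result adds little support. Less X-zone tissue in replicate 2 stays open, since 3 of the 4 genes lay below the random median, Pik3c2g at -0.20, Thrb at -0.22 and Cyp2f2 at -0.29, while the marker Akr1c18 lay at 0.12. With 1 library per animal it cannot be told apart from other differences between the animals, and no biological group was there to test it.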
